A study of Mus musculus with 25 samples.

How the data were processed

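Cells of a mouse macrophage line had been treated with HOCl in medium for 6 h at 7 doses from 0.14 to 3.5 mM or at 0 mM. RNA of each culture was hybridized to 1 Affymetrix mouse whole-genome array, 25 in all. Per the labels, cRNA was made from total RNA by a one-cycle protocol, intensities were read with Array Assist, and the authors used RMA; its version and settings are not given in the sources used here. The deposited values are log2 signals per probe set, from which the median of each array has been taken, so that every array has a median of 0. The labels do not state the base of the logarithm: base 2 was inferred from the span of the values, and every fold given rests on it. Quartiles differ between arrays, so the deposited values show no quantile normalization over the 25 arrays. The design text gives 3 replicates per dose, and the arrays number 4 at 0 mM. Raw intensity files were not used here.

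Of 45101 probe sets 64 control probe sets were set aside and 45037 tested, with no filter on signal. A gene was represented by the brightest of its probe sets that carry 1 symbol (34945 probe sets, 18193 genes), while 932 probe sets with several symbols and 9160 without a symbol counted as probe sets only. Gapdh has no such probe set among the tested ones and enters only through its control probe sets. A linear model with a mean per dose was fitted to all 25 arrays with limma 3.58.1 in R 4.3.3, and moderated tests with the default variance prior (17 residual and 2.99 prior degrees of freedom) were two-sided. P-values were adjusted by the method of Benjamini and Hochberg over the probe sets of each comparison, and an adjusted p under 0.05 was called. Each dose was compared with 0 mM and with the next lower dose, and an F test covered the 7 doses against 0 mM. Calls of different doses share the 0 mM arrays, and their overlap was not analysed here.

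Lists of 499 genes in 21 groups, 460 of them measured, were tested with camera at a preset correlation of 0.01 over 147 tests, and with an estimated correlation and with fry as alternatives. Member counts are given over all probe sets and adjusted over the list alone. The lists, tests, thresholds, alternatives and the rule for named genes were fixed before the data were examined, except where a later choice is stated. By that rule the named genes were, at each dose against 0 mM, the 5 largest rises and falls past the threshold with all arrays of the dose beyond all 0 mM arrays; at 2.1 mM, the dose with the most 2-fold changes, the 15 largest each way; up to 4 members of each list with the lowest F test p; at steps with calls, the 3 largest rises and falls; and a set of stress, inflammation and control genes whatever their result. Genes outside it are list members chosen after their values were seen.

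Alternatives were quantile normalization, centring on array medians, leaving out dim probe sets, a trended and robust variance prior, fitting only the groups compared, array weights, replicate number as a block, 1 probe set per gene, the probe set of largest variance, and leaving out each array in turn. Replicate numbers did not pair the arrays throughout: of 84 pairs of arrays with the same number, 19 had residuals correlated above 0.1 (median -0.0256, from -0.698 to 0.555). For 5 of 24 arrays the mean correlation was highest with arrays of their own number. Some pairs were more alike, such as number 3 of 0.7 and 1.4 mM (0.555) and of 0.35 and 0.7 mM (0.526), so a run shared by some doses is not excluded. Spike level as a term, fits within each spike level and gene-by-gene array weights were added after seeing the data. Arrays were assigned to spike levels by the mean of 8 probe sets at a threshold of 1.44. The steps were tested on simulated data with known changes: at the group sizes of 0.7 against 0 mM 51.3% of 1.5-fold, 85.7% of 2-fold and 98.1% of 4-fold changes were called, with 8 false calls (4.47% of calls), and at those of 3.5 against 2.8 mM 44.3%, 86.7% and 100%, with 8 false calls (4.76%). The simulated noise was independent between probe sets and between arrays. It held no array that stands apart and no spike levels, so these rates need not hold for the arrays here.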

Results

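Cells of a mouse macrophage line were exposed to hypochlorous acid (HOCl), the oxidant that neutrophils make with myeloperoxidase, for 6 h at 8 concentrations in culture medium. Transcripts were measured on 25 Affymetrix mouse whole-genome arrays, 4 at 0 mM and 3 at each of the 7 doses. The lower doses were 0.14, 0.35 and 0.7 mM, and the higher ones 1.4, 2.1, 2.8 and 3.5 mM. The labels call the replicates biological. The limma p-values below rest on the spread between such arrays within a dose, pooled over all 8 doses unless a smaller fit is named. They do not measure the spread of the compared doses alone, and the spread differed between doses. For the mean of the NF-kB inflammatory gene list the SD was 1.08 at 0.7 mM and 0.0365 at 3.5 mM. Camera p-values instead set the genes of a list against all other genes, at the preset correlation unless an estimated one is named. Values are log2 signals with an array median of 0, and the number of arrays limits their precision. Pairs of arrays of the same dose correlated across probe sets at r of 0.953 to 0.997, a measure of likeness between arrays in which probe sets are not independent replicates. The question was how expression changes with dose, so each dose was compared with 0 mM and with its lower neighbour. Folds and log2 changes are differences between dose means (n = 4 at 0 mM, n = 3 at every other dose), each with the standard error (SE) of the limma fit.

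A technical measure divided the arrays. The 8 probe sets for the 5' ends of Bacillus poly-A control transcripts had means of at most 1.12 on 11 arrays, which were all arrays of 0 and 0.14 mM and replicates 1 and 2 of 0.35 and 0.7 mM. On the other 14 arrays, replicate 3 of 0.35 and 0.7 mM and every array from 1.4 to 3.5 mM, they were at least 1.75. The labels name no batch. Spike level and dose coincide from 1.4 mM upwards, where a fit with spike level as a term rests on replicate 3 of 0.35 and 0.7 mM alone. This division was found after the values were seen.

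Over all doses the moderated F test of limma called 11114 of 45037 probe sets, for 5086 genes. With spike level as a term it called 6963. Of the 147 tests of 21 gene lists at 7 doses, camera called 54, of which 3 held with an estimated correlation between genes: the NRF2 antioxidant list at 0.7, 1.4 and 2.1 mM. Of the control genes for which values were to be given whatever their result, Actb did not pass the test at any dose and its log2 change ranged from -0.06 at 3.5 mM to 0.25 at 0.35 mM.

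**Figure D1:**
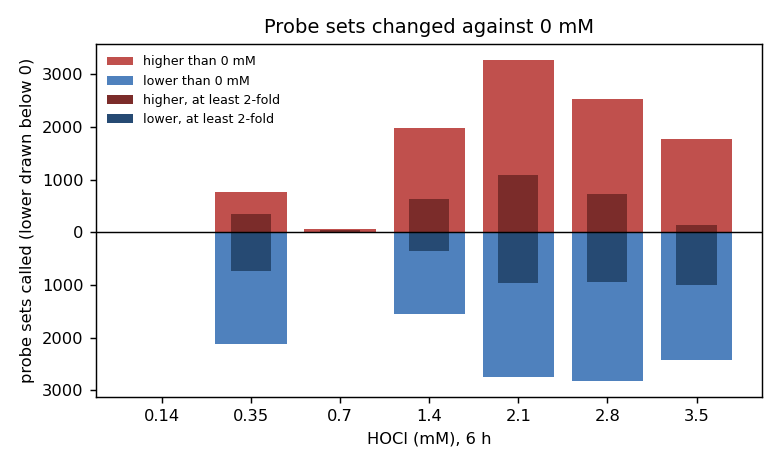
Probe sets called against 0 mM (vertical axis, number; lower drawn below 0) at each HOCl dose (horizontal axis, mM, not to scale); narrow bars are calls of at least 2-fold. The total was 2898 at 0.35 mM, 60 at 0.7 mM and 6015 at 2.1 mM, so it did not rise evenly with dose.

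At 0.14 mM, no member of the NRF2 antioxidant list, genes for glutathione, thioredoxin and quinone metabolism, passed the test over all probe sets, and 5 of 26 were higher when adjusted over the list alone. The list's median log2 change was 0.49 (camera, adjusted p = 5.69e-08; adjusted p = 0.165 with an estimated correlation), and Hmox1, heme oxygenase, had 0.42 (SE 0.203, adjusted p = 0.561). The single-gene test called Ddx17, an RNA helicase, which rose 2.2-fold (log2 1.14, SE 0.17, adjusted p = 0.0354), and Ranbp3l, which rose 1.6-fold (log2 0.68, SE 0.0839, adjusted p = 0.00435). Camera also called lower values for the immediate early list (median -0.53, adjusted p = 0.000547; 0 of 25 members, 0 adjusted over the list alone), the ATF4 list (median -0.33, adjusted p = 0.000764; 0 of 23, and 2 lower adjusted over the list alone) and the p53 list (median -0.33, adjusted p = 0.00764; 0 of 20, 0 adjusted over the list alone). With an estimated correlation their adjusted p were 0.791, 0.791 and 0.682. It called higher values for macrophage identity (median 0.24, adjusted p = 0.00313; 0.373 with an estimated correlation), DNA replication (median 0.34, adjusted p = 0.00483; 0.933 with an estimated correlation) and ribosomal protein genes (median 0.09, adjusted p = 0.0225; 0.933 with an estimated correlation), with 0 members called in each, over all probe sets or adjusted over the list alone.

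In the lists that camera called lower at 0.14 mM the 0 mM arrays were themselves split. The immediate early mean was -0.59 and -0.74 on 0 mM replicates 1 and 3, and 0.72 and 0.61 on replicates 2 and 4. The ATF4 and p53 means had the same signs on these arrays. For the immediate early and p53 lists every 0.14 mM array lay within the 0 mM range. Of the lists called higher, DNA replication was split as well, at 0.24 and 0.47 on 0 mM replicates 1 and 3 and -0.32 and -0.40 on replicates 2 and 4. In the DNA replication and ribosomal protein lists, too, every 0.14 mM array lay within the 0 mM range. Calls of these lists at other doses rest on the same 0 mM arrays. The test at 0.14 mM called 2 probe sets, 4009 having an unadjusted p under 0.05. The count was 56 without 0 mM replicate 3, 8 without 0 mM replicate 1 and 0 without 0.14 mM replicate 2 or 3 or within the low spike level. It was 1, with the Ddx17 call lost, without any of 0 mM replicates 2 and 4, 0.14 mM replicate 1, 0.35 mM replicate 1, 0.7 mM replicate 1, 1.4 mM replicate 2, 2.1 mM replicates 1, 2 and 3, 2.8 mM replicates 2 and 3 and 3.5 mM replicate 2.

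At 0.35 mM, the largest rises included inflammatory and interferon genes. Csf3, the granulocyte colony-stimulating factor, rose 159-fold (log2 7.31, SE 1.51, adjusted p = 0.0102). Fabp4 rose 75.8-fold (log2 6.24, SE 1.32, adjusted p = 0.0113), Acod1, which makes itaconate, 61.9-fold (log2 5.95, SE 1.29, adjusted p = 0.0123), Ifit1 44.4-fold (log2 5.47, SE 1.22, adjusted p = 0.0145) and the chemokine Ccl2 38.6-fold (log2 5.27, SE 1.16, adjusted p = 0.0135). Of the NF-kB inflammatory list 14 of 31 measured members were higher and 0 lower (19 higher and 2 lower adjusted over the list alone), among them Ptgs2, cyclooxygenase 2 (log2 4.03, adjusted p = 0.00745), Socs3 (3.48, adjusted p = 0.011) and Tnf (3.48, adjusted p = 0.0123). Of the interferon list 16 of 25 were higher (23 adjusted over the list alone), with Rsad2 at 4.65 (adjusted p = 0.0147) and Ifit3 at 4.50 (adjusted p = 0.0138). Both lists were called higher by camera, with medians of 1.25 (adjusted p = 4.58e-08; adjusted p = 0.58 with an estimated correlation) and 2.27 (adjusted p = 2.59e-15; adjusted p = 0.462 with an estimated correlation). The NF-kB list stood 1.77, 1.47 and 1.73 above the 0 mM mean on the 3 arrays of this dose. S100a8, counted among genes of other cell types, rose too (log2 4.17, adjusted p = 0.014), and the mean of that list was 0.25, 0.38 and 0.23 on the same arrays.

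The antioxidant list had 9 members higher and 2 lower out of 26 at 0.35 mM (12 and 3 adjusted over the list alone). The antioxidant median was 0.43, with a camera adjusted p of 0.00035 (adjusted p = 0.462 with an estimated correlation). Slc7a11, the cystine importer, rose 12.9-fold (log2 3.69, SE 0.487, adjusted p = 0.00235), Hmox1 4.9-fold (log2 2.29, SE 0.203, adjusted p = 1.78e-05) and Gclm, a subunit of the enzyme that starts glutathione synthesis, 4.29-fold (log2 2.10, SE 0.348, adjusted p = 0.005). The members that fell, Ephx1 (log2 -2.11), an epoxide hydrolase, and Gstm1 (-1.01), a glutathione transferase, were picked out after their values were seen, and 0 members were lower within the low spike level or with spike level as a term. Proteasome genes were higher for 7 of 31 members (16 adjusted over the list alone), Psmd11 among them at 0.58 (adjusted p = 0.0101). The proteasome median was 0.35, with a camera adjusted p of 5.5e-09 (adjusted p = 0.581 with an estimated correlation). In the heat shock list 1 of 19 was higher, Hsp90aa1 at 0.93 (adjusted p = 0.00963; 2 higher adjusted over the list alone), and camera called the list (median 0.39, adjusted p = 0.0272; adjusted p = 0.651 with an estimated correlation).

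Of the mitosis list 9 of 27 members were lower at 0.35 mM (18 adjusted over the list alone), with Cenpa, the centromeric histone, at -1.72 (adjusted p = 0.00983) and Prc1 at -1.64 (adjusted p = 0.0147). The mitosis median was -0.96, with a camera adjusted p of 7.92e-11 (adjusted p = 0.581 with an estimated correlation). Of the hypoxia and glycolysis list 7 of 21 were lower (11 adjusted over the list alone), with Ankrd37 at -3.13 (SE 0.624, adjusted p = 0.0091) and Egln1, an oxygen sensor, at -1.57 (adjusted p = 0.00804). The hypoxia and glycolysis median was -0.84, with a camera adjusted p of 6.64e-06 (adjusted p = 0.581 with an estimated correlation). Of the oxidative phosphorylation list 8 of 28 were lower (10 lower and 1 higher adjusted over the list alone), Uqcrfs1 at -0.48 (adjusted p = 0.0138). The oxidative phosphorylation median was -0.23, with a camera adjusted p of 4.63e-05 (adjusted p = 0.581 with an estimated correlation). Outside the lists Htr1b, a serotonin receptor, fell by 3.00 (SE 0.458, adjusted p = 0.00468) and Cldn11, a tight junction protein, fell by 2.74 (SE 0.523, adjusted p = 0.0075).

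The test at 0.35 mM called 2898 probe sets, 771 higher and 2127 lower (37.4% of calls higher after quantile normalization against 26.6%), of which 1078 changed at least 2-fold. It called 163 without 0.35 mM replicate 2, where Csf3, Fabp4, Acod1, Ifit1, Ccl2, Tnf, Socs3, Rsad2, Ifit3, Ankrd37, Egln1, Cldn11, Cenpa, Prc1 and Uqcrfs1 had adjusted p of 0.0555, 0.0567, 0.0588, 0.0621, 0.0604, 0.0588, 0.0553, 0.0604, 0.0604, 0.0555, 0.0571, 0.0553, 0.0569, 0.0748 and 0.0713. Of the 47 named calls 40 were lost without 1 array or another, and Hmox1, Gclm, Slc7a11, Ptgs2, Htr1b, Hsp90aa1 and Psmd11 passed in every omission. Without 0 mM replicate 2, where it called 789, Ifit1, Ifit3, Prc1 and Uqcrfs1 had adjusted p of 0.0515, 0.0506, 0.0529 and 0.0526. It called 4851 without 0 mM replicate 3, 1029 without 0 mM replicate 4, 1778 without 0.35 mM replicate 1 and 1851 within the low spike level, where 16 members of the NF-kB list, 14 of the interferon list and 8 of the antioxidant list were higher and 14 of the mitosis list lower. With spike level as a term these were 10, 8, 9 and 5. Other lists had fewer calls within the low level than in the fit of all arrays. There 0 of the oxidative phosphorylation list and 2 of the hypoxia and glycolysis list were lower, and 1 of the proteasome list and 0 of the heat shock list higher, with medians of -0.21, -0.90, 0.31 and 0.41. With the term these were 5, 4, 2 and 1. Of the 47 named calls 12 were lost within the low level and 14 with the term.

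At 0.7 mM, genes of the antioxidant list were higher. Slc7a11 rose 10.1-fold (log2 3.34, SE 0.487, adjusted p = 0.00346), Gclm 9.96-fold (log2 3.32, SE 0.348, adjusted p = 0.000109) and Hmox1 6.97-fold (log2 2.80, SE 0.203, adjusted p = 5.05e-07). Outside the list Slc40a1, the iron exporter ferroportin, rose 7.88-fold (log2 2.98, SE 0.361, adjusted p = 0.000814) and Afp, alpha-fetoprotein, 7.53-fold (log2 2.91, SE 0.537, adjusted p = 0.0287). Of the antioxidant list 11 of 26 were higher (17 adjusted over the list alone), including Srxn1, sulfiredoxin, at 2.51 (adjusted p = 0.0085), Txnrd1, thioredoxin reductase, at 1.22 (adjusted p = 0.0123) and Nqo1, a quinone reductase, at 1.96 (adjusted p = 0.0462). The antioxidant median was 1.18, with a camera adjusted p of 5.91e-25 (adjusted p = 0.0036 with an estimated correlation). Kif21b, a kinesin, fell by 1.37 (adjusted p = 0.0272), Etv5 fell by 1.05 (adjusted p = 0.0451) and Pwwp2b fell by 0.62 (adjusted p = 0.0201).

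In the other lists 0 members passed the limma test at 0.7 mM over all probe sets. Proteasome genes had a median of 0.29 (adjusted p = 2.41e-12; adjusted p = 0.462 with an estimated correlation; 12 of 31 higher adjusted over the list alone) and heat shock genes of 0.36 (adjusted p = 0.00343; adjusted p = 0.462 with an estimated correlation; 2 of 19 higher adjusted over the list alone). Camera also called the interferon (0.69, adjusted p = 0.009) and NF-kB (0.39, adjusted p = 0.0285) lists higher and the hypoxia and glycolysis (-0.36, adjusted p = 0.000783), mitosis (-0.26, adjusted p = 0.0088), immediate early (-0.49, adjusted p = 0.0088) and cholesterol synthesis (-0.12, adjusted p = 0.014) lists lower, each with 0 members adjusted over the list alone. With an estimated correlation their adjusted p was 0.791 for hypoxia and glycolysis and 0.933 for each of the others. The hypoxia and glycolysis mean was -0.60, -0.03 and -0.75 on replicates 1, 2 and 3, against -0.60 on 0 mM replicate 3, the lowest of 0 mM. The NF-kB list stood at 1.75 on replicate 3 and at -0.24 and 0.02 on replicates 1 and 2, and the interferon list at 2.43 on replicate 3 and at 0.33 and -0.68. Within the low spike level, without replicate 3, the interferon and NF-kB medians were -0.13 and -0.05 and the mitosis median -0.08.

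The test at 0.7 mM called 60 probe sets, 54 higher and 6 lower, of which 41 changed at least 2-fold. It called 25 within the low spike level, where 7 antioxidant genes were higher. It called 0 when only the arrays of 0 and 0.7 mM were fitted (3087 with an unadjusted p under 0.05). It called 708 without 0 mM replicate 3, 31 without 0 mM replicate 2, 19 without 0 mM replicate 4 or without 0.7 mM replicate 2, 37 without 0.7 mM replicate 3 and 98 without 2.8 mM replicate 1. Slc7a11, Gclm, Slc40a1 and Hmox1 passed with spike level as a term and without any single array. With the term Afp was at 2.50 (adjusted p = 0.0742), Kif21b at -1.33 (adjusted p = 0.0649), Etv5 at -0.94 (adjusted p = 0.117) and Pwwp2b at -0.57 (adjusted p = 0.059). These 4 and Nqo1 (adjusted p = 0.0903) were also lost within the low level. Without 0.7 mM replicate 2 the adjusted p of Srxn1 was 0.083, of Txnrd1 0.13 and of Afp 0.0796. Over all omissions 7 of the 11 named calls were lost without 1 array or another.

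At 1.4 mM, genes of the antioxidant, proteasome and heat shock lists were higher. Slc7a11 rose 20.1-fold (log2 4.33, SE 0.487, adjusted p = 7.09e-05), Srxn1 12.5-fold (log2 3.65, SE 0.395, adjusted p = 4.88e-05) and Gclm 11.4-fold (log2 3.51, SE 0.348, adjusted p = 3.17e-05). Outside these lists Afp rose 19.8-fold (log2 4.31, SE 0.537, adjusted p = 0.000166) and Procr, the protein C receptor, 16.4-fold (log2 4.04, SE 0.557, adjusted p = 0.000443). Of the antioxidant list 17 of 26 were higher (20 adjusted over the list alone). The antioxidant median was 1.18, with a camera adjusted p of 6.03e-20 (adjusted p = 0.00689 with an estimated correlation). Of the proteasome list 15 of 31 were higher (23 adjusted over the list alone), with Psmd7 at 1.30 (adjusted p = 0.00108) and Psmc1 at 0.92 (adjusted p = 0.00298). The proteasome median was 0.47, with a camera adjusted p of 4.22e-15 (adjusted p = 0.373 with an estimated correlation). Of the heat shock list 5 of 19 were higher (9 adjusted over the list alone), with Hsp90aa1 at 1.45 (adjusted p = 0.000267) and Chordc1 at 0.83 (adjusted p = 0.00389). The heat shock median was 0.45, with a camera adjusted p of 2.38e-05 (adjusted p = 0.226 with an estimated correlation).

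Among the genes that fell at 1.4 mM, Gpr183, an oxysterol receptor, fell by 2.37 (SE 0.453, adjusted p = 0.00446), Ptp4a3 fell by 2.12 (SE 0.389, adjusted p = 0.00349), Id3 fell by 1.91 (SE 0.375, adjusted p = 0.00534) and Rassf4 fell by 1.88 (SE 0.367, adjusted p = 0.00514). The mitosis list had 4 of 27 lower (12 adjusted over the list alone) and was at -1.40, -0.01 and -1.07 on replicates 1, 2 and 3. The mitosis median was -0.86, with a camera adjusted p of 4.31e-07 (adjusted p = 0.791 with an estimated correlation). The hypoxia and glycolysis list had 3 of 21 lower (3 adjusted over the list alone), Egln3 at -0.49 (adjusted p = 0.0111). The hypoxia and glycolysis median was -0.45, with a camera adjusted p of 0.0198 (adjusted p = 0.933 with an estimated correlation). Its mean was -0.03, -0.68 and -0.72 on replicates 1, 2 and 3, and from -0.60 to 0.45 on the 0 mM arrays. The NF-kB list had 1 of 31 higher, Ptgs2, and 1 lower, Relb, which encodes a subunit of NF-kB (2 and 3 adjusted over the list alone; median 0.38, adjusted p = 0.144), and was at 0.17, -0.17 and 1.63 on replicates 1, 2 and 3. The interferon list had 0 of 25 (0 adjusted over the list alone; median 0.30, adjusted p = 0.318) and was at -0.87, -0.19 and 2.13 on the same arrays.

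The test at 1.4 mM called 3519 probe sets, 1976 higher and 1543 lower (1001 at least 2-fold). Lower calls were the more frequent after quantile normalization (1966 higher and 2077 lower) and with 1 probe set per gene (734 and 990). It called 17 with spike level as a term, where 3 of 37 named calls passed (Srxn1, Gclm and Hmox1). Over the other 34 that term left a median of 0.689 of the change and made the SE 1.46 times as large. Rassf4 was then at -1.84 (SE 0.567 against 0.367; adjusted p = 0.432) and Ptgs2 at 1.48 against 3.33 (SE 1.04 against 0.764; adjusted p = 0.711). Ptgs2 is in the NF-kB list, which was high (1.75) on replicate 3 of 0.7 mM, an array on which the term rests. With the term 4 antioxidant genes and 0 of the proteasome, heat shock and mitosis lists passed, with medians of 1.58, 0.22, 0.39 and -0.69. The test called 2073 without 0 mM replicate 4 and 1699, 2212 and 2175 without 1.4 mM replicates 1, 2 and 3. The Ptgs2 call was lost without 1.4 mM replicate 1 (adjusted p = 0.0573) or 3 (adjusted p = 0.0639), and 17 of the 37 named calls were lost without 1 array or another.

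At 2.1 mM, Csf3 rose 76.8-fold (log2 6.26, SE 1.51, adjusted p = 0.00932), Fabp4 63.7-fold (log2 5.99, SE 1.32, adjusted p = 0.0054), Slc7a11 36.5-fold (log2 5.19, SE 0.487, adjusted p = 8.17e-06), Acod1 33.6-fold (log2 5.07, SE 1.29, adjusted p = 0.0128) and Procr 25.8-fold (log2 4.69, SE 0.557, adjusted p = 7.38e-05). Of the antioxidant list 16 of 26 were higher and 1, Ephx1, lower (21 and 2 adjusted over the list alone), with Srxn1 at 4.21 and Hmox1 at 3.51 (adjusted p = 7.76e-09). The antioxidant median was 1.31, with a camera adjusted p of 1.08e-14 (adjusted p = 0.024 with an estimated correlation). Of the proteasome list 26 of 31 were higher (29 adjusted over the list alone), Psmd7 at 1.49 (adjusted p = 0.000207). The proteasome median was 0.66, with a camera adjusted p of 6.03e-20 (adjusted p = 0.274 with an estimated correlation). Of the heat shock list 5 of 19 were higher (10 adjusted over the list alone), Hsph1 at 1.32 (adjusted p = 0.00383). The heat shock median was 0.51, with a camera adjusted p of 0.000239 (adjusted p = 0.349 with an estimated correlation).

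The NF-kB list at 2.1 mM had 13 of 31 higher and 1, Relb, lower (15 and 1 adjusted over the list alone), Ptgs2 at 4.34 (SE 0.764, adjusted p = 0.00124) and Rel, a subunit of NF-kB, at 2.35 (adjusted p = 0.00825). The NF-kB median was 0.75, with a camera adjusted p of 0.00015 (adjusted p = 0.791 with an estimated correlation). On the 3 arrays the NF-kB list was at 1.47, 1.38 and 1.31. The interferon list had 1 of 25 higher, Rsad2 at 3.77 (adjusted p = 0.0212; 1 adjusted over the list alone). The interferon median was 1.24, with a camera adjusted p of 0.00138 (adjusted p = 0.933 with an estimated correlation). Its mean was 1.34, 1.11 and 1.07 on the 3 arrays, and 1.19 on 0 mM replicate 3, within their range. Il1rn, the interleukin-1 receptor antagonist, rose 20.9-fold (adjusted p = 0.00725), Cxcl3 14.6-fold (adjusted p = 0.0064), Pdpn, podoplanin, 13.8-fold (adjusted p = 0.011) and Slc17a6, a glutamate transporter, 16.8-fold (adjusted p = 0.000987).

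Of the mitosis list 25 of 27 were lower at 2.1 mM (26 adjusted over the list alone). The mitosis median was -1.73, with a camera adjusted p of 1.55e-19 (adjusted p = 0.373 with an estimated correlation). Cenpf, a kinetochore protein, fell by 2.52 (SE 0.469, adjusted p = 0.00183), Prc1 fell by 2.34 (adjusted p = 0.000622) and Ube2c fell by 2.25 (adjusted p = 0.000272), and outside the list Aspm, a spindle pole protein, fell by 2.71 (adjusted p = 0.000527) and Psrc1 fell by 3.08 (adjusted p = 0.000452). Of the hypoxia and glycolysis list 7 of 21 were lower (11 adjusted over the list alone), Ankrd37 at -2.67 (adjusted p = 0.00788). The hypoxia and glycolysis median was -0.56, with a camera adjusted p of 0.00169 (adjusted p = 0.853 with an estimated correlation). Its mean was -0.61, -0.72 and -0.73 on replicates 1, 2 and 3, against -0.60 on 0 mM replicate 3, the lowest of 0 mM. Of the genes of largest fall, Selenbp1 fell by 4.79 (SE 1.23, adjusted p = 0.0135; adjusted p = 0.0512 without 2.1 mM replicate 1), Lsp1, a leukocyte actin-binding protein, fell by 3.18 (adjusted p = 0.00805), Frmd4b fell by 3.01 (adjusted p = 0.00192), Gpr183 fell by 2.97 (adjusted p = 0.000507), Eno2, an enolase, fell by 2.88 (adjusted p = 0.012), Cd24a fell by 2.74 (adjusted p = 0.00666) and Rnase4 fell by 2.65 (adjusted p = 0.00168).

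The test at 2.1 mM called 6015 probe sets, 3271 higher and 2744 lower (2045 at least 2-fold). Lower calls were the more frequent after quantile normalization (3060 higher and 3267 lower) and with 1 probe set per gene (1428 and 1557). It called 39 with spike level as a term, where 4 of 81 named calls passed (Slc7a11 at 4.28, Srxn1 at 4.56, Hmox1 at 3.85 and Gclm at 4.29) and 0 of the proteasome and mitosis lists and of the NF-kB list. Over the other 77 the change was a median of 0.706 of that without the term and the SE 1.47 times as large. The mitosis median was then -1.44 and the proteasome median 0.46, whereas those of the NF-kB and interferon lists were 0.34 and -0.21. Replicate 3 of 0.7 mM, an array on which the term rests, had means of 1.75 and 2.43 for the NF-kB and interferon lists. On replicates 1 and 2 of 0.7 mM they were -0.24 and 0.02 (NF-kB) and 0.33 and -0.68 (interferon). In these lists the term therefore cannot tell spike level from the state of that array. With the term Procr was at 3.98 (SE 0.834, adjusted p = 0.0885), Frmd4b at -3.07 (SE 0.874, adjusted p = 0.201) and Csf3 at 2.73 (SE 2.07, adjusted p = 0.614). The test called 3243, 3120 and 3424 without 2.1 mM replicates 1, 2 and 3. The Rsad2 call was lost without 2.1 mM replicate 1, 2 or 3 (adjusted p = 0.0715, 0.0638 and 0.0645) or 0 mM replicate 1 (0.0572), and 26 of the 81 named calls were lost without 1 array or another.

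**Figure D2:**
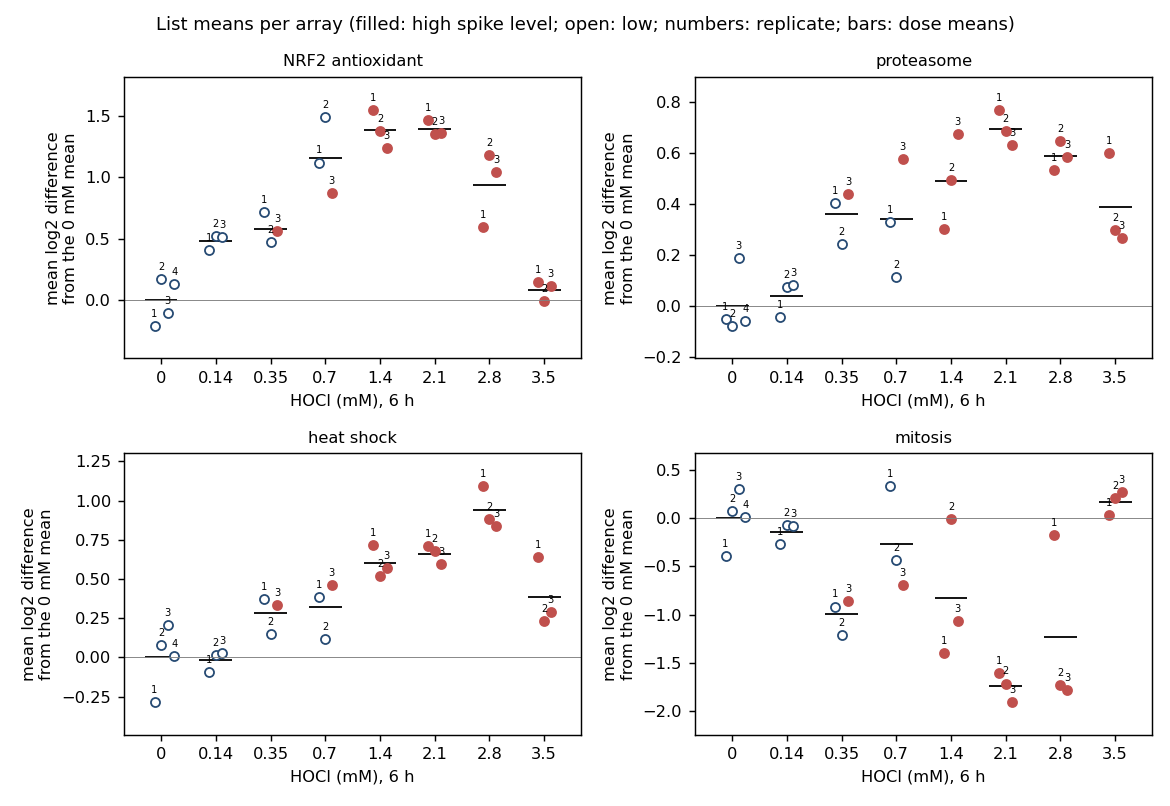
Mean log2 difference from the 0 mM mean over the members of 4 gene lists (vertical axes) on each array, by HOCl dose (horizontal axes, mM, not to scale); points are arrays with their replicate number, filled for the high spike level, and short lines are dose means. The antioxidant mean was 0.48 at 0.14 mM, 1.39 at 1.4 and 2.1 mM and 0.09 at 3.5 mM.

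At 2.8 mM, Hspa1b, an inducible HSP70, rose 12.3-fold (log2 3.62, SE 0.581, adjusted p = 0.000676), and 8 of 19 heat shock genes were higher (14 adjusted over the list alone), with Hsp90aa1 at 1.64 (adjusted p = 7.61e-05) and Hsph1 at 1.49 (adjusted p = 0.00187). The heat shock median was 0.73, with a camera adjusted p of 9.74e-08 (adjusted p = 0.0977 with an estimated correlation). Procr rose 15-fold (log2 3.91, SE 0.557, adjusted p = 0.000268) and Slc7a11 13.4-fold (log2 3.75, SE 0.487, adjusted p = 0.000159). Of the antioxidant list 10 of 26 were higher (14 higher and 1 lower adjusted over the list alone) and of the proteasome list 23 of 31 (26 adjusted over the list alone). The antioxidant median was 0.75, with a camera adjusted p of 1.02e-08 (adjusted p = 0.138 with an estimated correlation). The proteasome median was 0.54, with a camera adjusted p of 6.49e-17 (adjusted p = 0.359 with an estimated correlation). Of the immediate early list 6 of 25 were higher and 1, Klf2, a transcription factor, lower (8 and 1 adjusted over the list alone), with Gadd45b at 3.24 (SE 0.328, adjusted p = 2.96e-05), Dusp2, a MAP kinase phosphatase, at 2.43 (adjusted p = 8.39e-05) and Fosl1 at 1.96 (adjusted p = 0.0024). The immediate early median was 0.42, with a camera adjusted p of 0.0272 (adjusted p = 0.933 with an estimated correlation). Its mean was 1.00, 0.33 and 0.41 on replicates 1, 2 and 3, against 0.72 on 0 mM replicate 2, the highest of 0 mM.

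The NF-kB list at 2.8 mM had 5 of 31 higher and 2 lower, Relb and the apoptosis inhibitor Birc3 (10 and 2 adjusted over the list alone), and was at 0.04, 1.45 and 1.35 on replicates 1, 2 and 3. The NF-kB median was 0.64, with a camera adjusted p of 0.00693 (adjusted p = 0.933 with an estimated correlation). The mitosis list had 16 of 27 lower (23 adjusted over the list alone), Cenpf at -2.39 (adjusted p = 0.00282), and was at -0.17, -1.73 and -1.78 on the same arrays. The mitosis median was -1.16, with a camera adjusted p of 1.12e-11 (adjusted p = 0.581 with an estimated correlation). The hypoxia and glycolysis list had 6 of 21 lower (7 adjusted over the list alone), Egln1 at -1.58 (adjusted p = 0.0024). The hypoxia and glycolysis median was -0.55, with a camera adjusted p of 0.00617 (adjusted p = 0.933 with an estimated correlation). Its mean was -0.43, -0.57 and -0.61 on replicates 1, 2 and 3, and -0.60 on 0 mM replicate 3, so replicates 1 and 2 lay within the 0 mM range. The interferon list had 1 of 25 lower, Irf7 (0 adjusted over the list alone; median 0.35, adjusted p = 0.562). Gpr183 fell by 3.65 (SE 0.453, adjusted p = 0.000119), Frmd4b fell by 3.17 (SE 0.564, adjusted p = 0.00147) and Id3 fell by 2.49 (SE 0.375, adjusted p = 0.000418).

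The test at 2.8 mM called 5357 probe sets, 2539 higher and 2818 lower (1666 at least 2-fold). It called 119 with spike level as a term, where 6 of 56 named calls passed (Hmox1, Gclm, Srxn1, Sel1l, Gadd45b and Bcl2). For the other 50 the change was a median of 0.696 of that without the term and the SE 1.47 times as large. Frmd4b was then at -3.23 (SE 0.874, adjusted p = 0.0963), Hspa1b at 3.22 (SE 0.891, adjusted p = 0.101) and Procr at 3.20 (SE 0.834, adjusted p = 0.0886). Of the lists 3 antioxidant genes were higher and 0 of the proteasome, heat shock, mitosis and NF-kB lists passed, with medians of 1.11, 0.36, 0.76, -1.04 and 0.01. The test called 2198 without 2.8 mM replicate 2 and 2266 without 2.8 mM replicate 3. Of the 56 named calls 24 were lost without 1 array or another.

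At 3.5 mM the pattern was a different one. H3f3b, which encodes histone H3.3, rose 22.8-fold (log2 4.51, SE 0.379, adjusted p = 3.59e-07), the histone gene H3c7 19.3-fold (log2 4.27, SE 0.246, adjusted p = 3.48e-09), 3110040M04Rik 16.3-fold (log2 4.03, SE 0.437, adjusted p = 7.26e-06), Hspa1b 14.3-fold (log2 3.84, SE 0.581, adjusted p = 0.000236) and Gadd45g 11.6-fold (log2 3.54, SE 0.515, adjusted p = 0.000159). Hipk2, a nuclear kinase, fell 9.95-fold (log2 -3.32, SE 0.253, adjusted p = 8.57e-08), Rbm39, a splicing factor, 6.34-fold (log2 -2.67, SE 0.388, adjusted p = 0.000161), Fosl2 5.73-fold (log2 -2.52, SE 0.441, adjusted p = 0.000949), Hivep3 5.02-fold (log2 -2.33, SE 0.354, adjusted p = 0.000249) and Zmat3, a p53 target, 4.98-fold (log2 -2.32, SE 0.379, adjusted p = 0.000514). Of the calls of at least 2-fold, 1005 of 1153 were lower.

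The antioxidant list at 3.5 mM had 1 of 26 higher, Taldo1, and 1 lower, Txnrd1 at -0.86 (1 and 1 adjusted over the list alone; median 0.11, mean 0.09, tested as lower by camera, adjusted p = 0.813), and Hmox1 was at -0.24 (SE 0.203, adjusted p = 0.486). Mitosis genes had 0 of 27 called (0 adjusted over the list alone; median 0.17, tested as lower by camera, adjusted p = 0.972) and interferon genes 0 of 25 (0 adjusted over the list alone; median 0.15, tested as lower, adjusted p = 0.805). The NF-kB list had 0 higher and 2 lower, the chemokine Ccl4 and the NF-kB inhibitor Nfkbia at -0.74 (0 and 1 adjusted over the list alone; median 0.02, mean -0.09, adjusted p = 0.167), with -0.08, -0.13 and -0.06 on the 3 arrays. Proteasome genes were higher for 15 of 31 (19 adjusted over the list alone), Psma7 at 0.78 (adjusted p = 0.000662), and oxidative phosphorylation genes for 9 of 28 (16 adjusted over the list alone), Uqcrc2 at 0.66 (adjusted p = 0.000866) and Ndufs4 at 0.61 (adjusted p = 0.00138). The proteasome median was 0.38, with a camera adjusted p of 2.6e-08 (adjusted p = 0.581 with an estimated correlation). The oxidative phosphorylation median was 0.30, with a camera adjusted p of 6.64e-08 (adjusted p = 0.451 with an estimated correlation). The heat shock list had 2 of 19 higher and 1, the cochaperone Bag3, lower (2 and 1 adjusted over the list alone; median 0.19, adjusted p = 0.637), and the hypoxia and glycolysis list 0 of 21 (0 adjusted over the list alone; median -0.04, adjusted p = 0.245). Replicate 1 of 3.5 mM stood apart from replicates 2 and 3 in the hypoxia and glycolysis list (-0.60 against 0.25 and 0.28), the ATF4 list (-0.32 against 0.55 and 0.82), the proteasome list (0.60 against 0.30 and 0.27) and the heat shock list (0.64 against 0.23 and 0.29). The immediate early list had 3 of 25 higher, among them Gadd45b at 1.67 (adjusted p = 0.00257), and 3 lower, Dusp4 at -0.96 among them (3 and 6 adjusted over the list alone). The immediate early median was -0.30, with a camera adjusted p of 0.00668 (adjusted p = 0.933 with an estimated correlation). Its mean was -0.17, -0.34 and -0.10 on replicates 1, 2 and 3, within the 0 mM range of -0.74 to 0.72.

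The test at 3.5 mM called 4199 probe sets, 1768 higher and 2431 lower (826 and 879 genes by the brightest probe set). No omitted array moved the count of probe sets that the test called by over 1.5 times. With spike level as a term it called 2624, 545 higher and 2079 lower, with 0 proteasome genes (median 0.18) and 1 oxidative phosphorylation gene (median 0.28) higher. In that fit 18 of the 31 named calls passed, among them H3f3b at 3.99, H3c7 at 4.15, Hspa1b at 3.44, Hipk2 at -3.55 and Rbm39 at -3.34. The Nfkbia call was lost without 3.5 mM replicate 3 (adjusted p = 0.0658) and its direction turned with the probe set of largest variance (0.35). The Txnrd1 call was lost without 3.5 mM replicate 2 (adjusted p = 0.0651) or 3 (adjusted p = 0.055), and 9 of the 31 named calls were lost without 1 array or another.

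**Figure D3:**
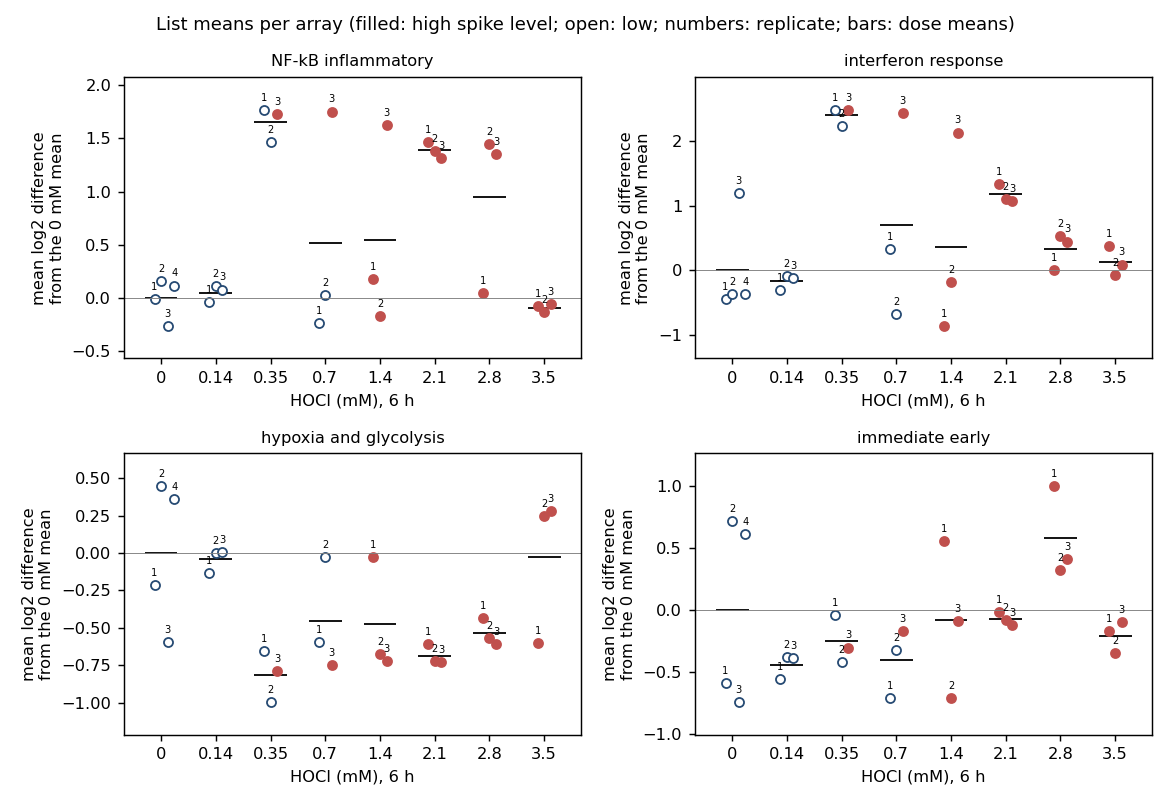
Mean log2 difference from the 0 mM mean over the members of 4 further gene lists (vertical axes) on each array, by HOCl dose (horizontal axes, mM, not to scale), with points, fills and lines as in the plot of the antioxidant list. The NF-kB mean was between 1.31 and 1.77 on every array of 0.35 and 2.1 mM and on 0.7 mM replicate 3, 1.4 mM replicate 3 and 2.8 mM replicates 2 and 3, and at most 0.17 on the other arrays.

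Neighbouring doses were also compared. Between 0.14 and 0.35 mM, Csf3 rose 174-fold (log2 7.45, SE 1.61, adjusted p = 0.0189), Fabp4 74.6-fold (log2 6.22, SE 1.41, adjusted p = 0.022) and Ifi209, an interferon-induced gene, 40.2-fold (log2 5.33, SE 1.17, adjusted p = 0.0201). Lsp1 fell by 3.42 (adjusted p = 0.0251), Cldn11 fell by 3.36 (adjusted p = 0.00815) and Htr1b fell by 3.18 (adjusted p = 0.00554). The step called 1517 probe sets, 495 higher and 1022 lower (49.2% of calls higher after quantile normalization against 32.6%). It called 697, 25 and 28 without 0.14 mM replicates 1, 2 and 3 and 545, 318 and 860 without 0.35 mM replicates 1, 2 and 3. With spike level as a term it called 512, and Csf3, Fabp4, Ifi209 and Lsp1 had adjusted p of 0.0545, 0.0645, 0.0546 and 0.0713. Within the low spike level it called 1439, 593 higher and 846 lower, and all 6 genes passed, with 16 NF-kB and 17 interferon genes higher and 8 mitosis genes lower. With the term these were 3, 2 and 0. Htr1b alone of the 6 passed without any single array. Without 0.14 mM replicate 2 the other 5 had adjusted p from 0.059 (Cldn11) to 0.106 (Lsp1).

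Between 0.35 and 0.7 mM, 0.7 and 1.4 mM, and 1.4 and 2.1 mM limma called 0 probe sets, with 2990, 4025 and 1343 at an unadjusted p under 0.05. The first of these steps gave 296 without 0.7 mM replicate 3 and 444 within the low spike level, where 13 of 31 NF-kB genes and 10 of 25 interferon genes were lower at 0.7 mM than at 0.35 mM. The next gave 4 without 1.4 mM replicate 3. Between 2.1 and 2.8 mM, 11 probe sets were called, with Arc up 7.42-fold (log2 2.89, SE 0.458, adjusted p = 0.0191), Gadd45b 5.78-fold (log2 2.53, SE 0.351, adjusted p = 0.00836) and Glul, glutamine synthetase, 2.76-fold (log2 1.46, SE 0.236, adjusted p = 0.0212). This count was 43 without 1.4 mM replicate 1, 1, 0 and 2 without 2.1 mM replicates 1, 2 and 3, 3 without 2.8 mM replicate 3 and 6 within the high spike level, where the adjusted p of Arc, Gadd45b and Glul were 0.212, 0.128 and 0.149. Without 2.1 mM replicate 2 they were 0.171, 0.0875 and 0.171, and without 2.8 mM replicate 1 those of Arc and Glul were 0.0989 and 0.184.

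Between 2.8 and 3.5 mM, H3c7 rose 12.6-fold (log2 3.65, SE 0.263, adjusted p = 1.22e-07) and H3f3b 10.5-fold (log2 3.39, SE 0.406, adjusted p = 3.38e-05), whereas Procr fell by 4.40 (SE 0.595, adjusted p = 0.00011) and Srxn1 fell by 3.70 (SE 0.422, adjusted p = 2.26e-05). Of the mitosis list 20 of 27 were higher at 3.5 mM (26 adjusted over the list alone; median 1.39, adjusted p = 0.432 with an estimated correlation) and of the oxidative phosphorylation list 12 of 28 (16 adjusted over the list alone; median 0.35, adjusted p = 0.432 with an estimated correlation). Of the antioxidant list 9 of 26 were lower (13 lower and 1 higher adjusted over the list alone; median -0.71, adjusted p = 0.217 with an estimated correlation), of the heat shock list 6 of 19 (7 adjusted over the list alone; adjusted p = 0.217 with an estimated correlation) and of the immediate early list 9 of 25, with 1 higher, Fos (12 and 1 adjusted over the list alone; adjusted p = 0.432 with an estimated correlation). With the preset correlation the adjusted p of these lists were 1.5e-10, 5.88e-06, 6.31e-09, 3.28e-06 and 1.83e-06 in the same order.

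The step to 3.5 mM called 5066 probe sets, 2518 higher and 2548 lower (1732 and 1030 with 1 probe set per gene), and 2123, 2177, 3127 and 2489 without 2.8 mM replicates 2 and 3 and 3.5 mM replicates 2 and 3. Within the high spike level 9 mitosis genes and 12 oxidative phosphorylation genes were higher and 10 antioxidant genes lower.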

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

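The tests of the 3 patterns weighed here were all chosen after the results were seen, while the counts of other splits of the arrays were planned.

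Genes of the NF-kB and interferon lists were high on some arrays and low on others of the same dose. A labelling batch marked by the spike controls is excluded as the whole cause: at 1.4 and 2.8 mM all arrays have the high spike level, yet the range of the NF-kB list within these doses was at least 8.81 times that at 2.1 mM. A run shared by replicate number that raises the NF-kB list on number 3 at every dose was not seen. Number 3 deviated from its dose mean of the NF-kB list by 1.24, 1.09 and 0.405 at 0.7, 1.4 and 2.8 mM, but by -0.265, 0.0284 and 0.0307 at 0, 0.14 and 3.5 mM, where the list was low on every array (SD 0.19, 0.0756 and 0.0365). Numbers 1 and 2 deviated by -0.751 and -0.49 at 0.7 mM, -0.371 and -0.716 at 1.4 mM and -0.904 and 0.499 at 2.8 mM. The doses 0, 0.14 and 3.5 mM were picked because the NF-kB list was low on every array, number 3 included. They cannot exclude a run that acts at 0.7, 1.4 and 2.8 mM. Such a run stays open, and the interferon list was high on number 3 also at 0 mM. Differences between the cultures or arrays of a dose, a mislabelled sample among them, may remain and were not tested, nor was a biological explanation. The inflammatory changes at 0.7, 1.4 and 2.8 mM are therefore open as to dose. At 0.35 and 2.1 mM the NF-kB list was high on every array (1.47 to 1.77 and 1.31 to 1.47). A difference between cultures that is unrelated to dose was not tested there either, so these changes are open too.

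The NRF2 list had medians of 0.49, 0.43, 1.18, 1.18 and 1.31 above 0 mM from 0.14 to 2.1 mM. The spike level is excluded as the whole cause at 0.7 mM, where 7 genes of the list were higher within the low spike level. At 1.4 to 2.8 mM the spike level and the dose are confounded, and with spike level as a term 4, 7 and 3 genes of the list were higher. The medians were then 1.58, 1.5 and 1.11 (1.18, 1.31 and 0.75 without it), so fewer calls came with no smaller medians. Single genes went both ways: Slc7a11 was at 3.42, 4.28 and 2.83 (4.33, 5.19 and 3.75 without the term). Hmox1 was at 3.64, 3.85 and 3.23 (3.31, 3.51 and 2.89 without it). The term rests on 2 arrays there, and a labelling batch stays open at those doses. An effect of HOCl is a hypothesis from the same data.

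Probe sets were mostly lower at 3.5 mM among 2-fold changes (1005 of 1153). Among calls of any size, with the brightest probe set for each gene, 826 genes were higher and 879 lower, which is close to even. RNA degradation stays open. The 3' minus 5' difference of the Gapdh control probe sets was -0.0612 ± 0.00457 (SD, n = 3), against -0.0464 ± 0.0945 on the other 22 arrays. That of Actb was 0.464 ± 0.205 against 0.403 ± 0.107, with 3.5 mM replicate 2, at 0.682, above all other arrays and replicate 3, at 0.276, below their mean. With 2 control genes that differ in this, degradation and regulation cannot be told apart. A lower yield of mRNA hidden by the centring may remain: the spike level was 0.00444 above that of 1.4 to 2.8 mM, but the step and the amount of RNA at which the controls were added are not given in the sources used here, so yield and regulation cannot be told apart. A biological effect of the highest dose was not separated from it.

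At 0 mM 17 of 164 measures had 1 array far from the other 3, where chance flags about 1 in 20 groups, or 8.2 here. The measures come from the same arrays and are not independent, and some of the genes were chosen by a rule that uses the 0 mM values. An excess over chance therefore cannot be read from 17 against 8.2. Replicate 3 was apart for the interferon list (1.19, others -0.455 to -0.365), the proteasome list (0.188), Ifit1 (2.81), Lsp1 (2.35), Rassf4 (2.79), Egln1 (2.74), Uqcrfs1 (5.44), Adgre1 (2.06) and Map1lc3b (4.7). Replicate 1 was apart for the metal response list (-0.316), the Gapdh 3' minus 5' difference (0.355), Ranbp3l (0.0194), Il1rn (3.12), Slc17a6 (1.2), Mtf1 (0.958) and Cenpa (4.54), and replicate 4 for Hivep3 (2.5). List values are differences from the 0 mM mean and gene values are log2 signals.

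The Bacillus poly-A control transcripts, which the comparisons do not use, were above their 0 mM mean of 0.991 at 0.35 mM (1.2), 0.7 mM (1.41), 1.4 mM (2), 2.1 mM (2.15), 2.8 mM (2.05) and 3.5 mM (2.07). At 0.35 and 0.7 mM replicate 3 alone lifted the mean (1.75 and 2.22). Replicates 1 and 2 of these doses lay below the highest 0 mM array (1.12).

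The 7 arrays of each dose and 0 mM were also split in other ways, 35 splits with the real one. They argue against chance for each count at 1.4 to 3.5 mM taken alone. The share reached is the smallest that 35 splits can give, and it was not corrected for the number of counts. There the real count was the highest of all splits: 3519 against 2247 at most at 1.4 mM, 6015 against 3719 at 2.1 mM, 5357 against 3798 at 2.8 mM and 4199 against 2334 at 3.5 mM, and for 2-fold changes 1001 against 702, 2045 against 1313, 1666 against 1219 and 1153 against 802, each with 1 split as large, the real one. Chance is not excluded at 0.14 mM (2 against 370, and 1 against 96 for 2-fold changes; 3 splits as large in each), 0.35 mM (2898 against 4174, and 1078 against 1277; 2 splits) or 0.7 mM (60 against 1293, and 41 against 375; 4 splits). In every one of these comparisons the highest other split set 0 mM replicates 1, 2 and 4 against the treated arrays with 0 mM replicate 3, and at 0.14 and 0.7 mM it called many times the real count, a structure among the 0 mM arrays. That split keeps the treated arrays together, so it still holds part of any dose difference. For the steps the 10 splits are too few for a share under 0.05; the real counts and the highest others were 1517 and 1 (0.35 mM), 0 and 982 (0.7 mM), 0 and 280 (1.4 mM), 0 and 0 (2.1 mM), 11 and 0 (2.8 mM) and 5066 and 100 (3.5 mM), with 1, 10, 10, 10, 1 and 1 splits as large. For the F test the real count was the highest of 100 splits (11114 against 2167), which argues against chance. For the number of lists called by camera chance is not excluded (54 against 69, with 34 of 100 splits as large).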

How the results depend on the processing

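The fits with spike level as a term, within each spike level and with gene-by-gene array weights were chosen after seeing the data. Doses are against 0 mM unless a step is named, and a count of at least 2-fold changes follows a count as "2-fold". For each shift the cause was not tested, except where fewer arrays or probe sets entered the fit. The trended and robust prior moved no total by over 1.5 times, and quantile normalization moved only the total of the step from 2.1 to 2.8 mM, to 17. Of the calls in 1 direction outside that step, quantile normalization moved the higher ones at 0.35 mM (771 to 1196) and at the step to 0.35 mM (495 to 1028). It also moved the lower ones at 0.7 mM (6 to 10), and the prior moved the last to 3. Centring on array medians leaves the values almost as they were, since the deposited medians are 0, and tests nothing. The signal of the arrays over background was not measured, and dim genes are limited by it.

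With spike level as a term the counts were 4 at 0.14 mM, 17 at 1.4 mM (2-fold 15), 39 at 2.1 mM (2-fold 33), 119 at 2.8 mM (2-fold 99), 2624 at 3.5 mM, 512 from 0.14 to 0.35 mM, 1 from 0.35 to 0.7 mM, 17 from 2.1 to 2.8 mM and 6963 by the F test. Within the low level, with 11 arrays, they were 0 at 0.14 mM (2-fold 0; limma, 3375 at an unadjusted p under 0.05), 1851 at 0.35 mM, 25 at 0.7 mM (2-fold 23) and 444 from 0.35 to 0.7 mM, and within the high level 6 from 2.1 to 2.8 mM.

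With only the groups compared the limma counts were 0 at 0.14 mM (2-fold 0; 3328 unadjusted), 774 at 0.35 mM (2-fold 532), 0 at 0.7 mM (2-fold 0; 3087 unadjusted), 1346 at 1.4 mM (2-fold 533), 2189 at 2.8 mM (2-fold 903) and 1819 at 3.5 mM, and at the steps to 0.35, 2.8 and 3.5 mM 2815, 143 and 2043. Without dim probe sets the count at 0.14 mM was 0 (2-fold 0; limma, 2129 unadjusted). With replicate number as a block, which the arrays do not bear out as a pairing, they were 0 at 0.14 mM (2-fold 0; limma, 2928 unadjusted), 950 at 0.35 mM (2-fold 519), 21 at 0.7 mM (2-fold 15), 1704 at 1.4 mM, 3990 at 2.1 mM and 3387 at 2.8 mM.

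With 1 probe set per gene, and so fewer tested, they were 1551 at 0.35 mM (2-fold 576), 30 at 0.7 mM (2-fold 24), 1724 at 1.4 mM (2-fold 454), 2985 at 2.1 mM (2-fold 1013), 2783 at 2.8 mM (2-fold 856) and 1636 at 3.5 mM (2-fold 386), at the steps to 0.35, 2.8 and 3.5 mM 809, 6 and 2762, and by the F test 5194.

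Array weights raised most counts. By the default method, which stopped before convergence and gave 0.35 mM replicate 1 a weight of 95.6, they were 8567 at 0.14 mM (2-fold 599), 22330 at 0.35 mM (2-fold 2174), 12435 at 0.7 mM (2-fold 1039), 9288 at 1.4 mM (2-fold 1772), 16406 at 2.1 mM, 13750 at 2.8 mM (2-fold 3075) and 7409 at 3.5 mM, at the steps to 0.35, 0.7, 1.4, 2.8 and 3.5 mM 20057, 18426, 5720, 1014 and 10739, and by the F test 37804. Gene by gene they were 8350 (2-fold 616), 11142 (2-fold 2184), 7939 (2-fold 955), 9263 (2-fold 1791), 17428, 14141 (2-fold 3132) and 7333 from 0.14 to 3.5 mM, 7463, 1585, 1146, 1816 and 11012 at the same steps, and 27997 by the F test.

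Leaving out 1 array gave 0 to 56 at 0.14 mM (2-fold 0 to 17), 163 to 4851 at 0.35 mM (2-fold 96 to 1794), 19 to 708 at 0.7 mM (2-fold 15 to 276), 1699 to 4123 at 1.4 mM (2-fold 699 to 1382), 3120 to 6630 at 2.1 mM (2-fold 1534 to 2469), 2198 to 6128 at 2.8 mM (2-fold 949 to 2428) and 2817 to 4718 at 3.5 mM (2-fold 926 to 1422). At the steps to 0.35, 0.7 and 1.4 mM the ranges were 25 to 2061, 0 to 296 and 0 to 4. At those to 2.1, 2.8 and 3.5 mM they were 0 to 0, 0 to 43 and 2123 to 6637, by the F test 8912 to 12722 and for the lists 47 to 56. Both extremes at 0.35 mM came from 0.35 mM replicate 2 (163) and 0 mM replicate 3 (4851). Of the 147 list tests an estimated correlation gave 3 calls and fry 24, against 54.

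Of 280 calls of named genes 196 fell short of the threshold with spike level as a term, 94 with only the groups compared, 67 with the replicate block, 10 after quantile normalization, 4 with the trended prior, and 3 with array weights of either kind, each in the same direction; over the omissions of 1 array 638 tests fell short, 6362 did not and 0 reversed. The probe set of largest variance ended 25 and reversed 7: Sel1l (0.0634) and Dnajc3 (-0.391) at 2.8 mM, Dnajc3 (-0.18) and Map1lc3b (-0.31) at 2.1 mM, and Nfkbia (0.35), Hmgcs1 (1.40) and Xiap (0.0635) at 3.5 mM.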

Other observations

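The values here are of gene lists and genes not described with the comparisons above; members outside the rule for named genes were chosen after their values were seen, and no explanation is offered for them.

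Few chaperone and stress genes of the endoplasmic reticulum passed at any dose. Camera called their list higher at 0.35 mM (median 0.53, adjusted p = 0.000547; adjusted p = 0.791 with an estimated correlation; 0 of 18 members by limma, 0 adjusted over the list alone) and at 2.1 mM (median 0.57, adjusted p = 0.00313; adjusted p = 0.895 with an estimated correlation; 2 higher, 3 adjusted over the list alone), where Dnajc3 was at 1.34 and Pdia3 at 0.65, the Dnajc3 change turning with the probe set of largest variance (-0.18). With spike level as a term 0 passed at 2.1 mM (median 0.18). At 2.8 mM 2 were higher and 2 lower, Sel1l and Syvn1 (3 and 2 adjusted over the list alone; adjusted p = 0.112), the Sel1l change turning with the probe set of largest variance (0.06), and at 3.5 mM 0 higher and 2 lower, Syvn1 at -1.67 and Sel1l at -0.76 (0 and 2 adjusted over the list alone; adjusted p = 0.637, median 0.27, tested as lower). The ATF4 list was not called above 0.14 mM, and Pck2, a gluconeogenic enzyme, was at -1.73 at 2.1 mM and -2.28 at 2.8 mM, with Chac1, which degrades glutathione, at 1.70 at 0.35 mM and 1.59 at 2.1 mM.

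The p53 list was called lower at 3.5 mM (median -0.24, adjusted p = 0.00668; adjusted p = 0.682 with an estimated correlation; 1 of 20 higher and 3 lower, 1 and 4 adjusted over the list alone), where Zmat3 was at -2.32 and Gadd45a at 2.12. At 2.8 mM 4 of its members were higher and 3 lower (5 and 3 adjusted over the list alone; adjusted p = 0.355), with Mdm2 at 1.34 and Gadd45a at 2.48. On replicates 1, 2 and 3 of 3.5 mM the mean of the p53 list was -0.45, -0.29 and -0.15, within the 0 mM range of -0.63 to 0.49. Cdkn1a, a cell cycle inhibitor, did not pass at any dose.

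DNA replication genes were called lower by camera at 1.4 mM (median -0.35, adjusted p = 0.0189; adjusted p = 0.933 with an estimated correlation; 1 of 29 higher and 1 lower, 0 adjusted over the list alone) and 2.1 mM (median -0.32, adjusted p = 0.0225; adjusted p = 0.933 with an estimated correlation; 1 higher and 4 lower, 1 and 5 adjusted over the list alone). Replicate 1 of 1.4 mM stood apart in this list, with a mean of -1.245 against 0.12 and -0.11 on replicates 2 and 3. On replicates 1, 2 and 3 of 2.1 mM the mean was -0.31, -0.39 and -0.54, and on the 0 mM arrays from -0.40 to 0.47. At 2.1 mM Mcm7, a helicase subunit, was at -1.15 and Tk1, thymidine kinase, at -1.79, while Pcna was at 0.50. Cholesterol synthesis genes were called lower at 0.35 mM (median -0.18, adjusted p = 0.0323; adjusted p = 0.933 with an estimated correlation; 1 of 20 lower, 4 adjusted over the list alone) and had 1 higher and 6 lower at 2.1 mM (1 and 6 adjusted over the list alone; adjusted p = 0.158), with Mvd at -1.31.

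Ribosomal protein genes were called higher at 1.4 mM (median 0.12, adjusted p = 0.0088; adjusted p = 0.933 with an estimated correlation; 0 of 20 by limma, 0 adjusted over the list alone) and at 3.5 mM (median 0.18, adjusted p = 0.00106; adjusted p = 0.933 with an estimated correlation; 1 higher, Rps6 at 0.58, 0 adjusted over the list alone). Macrophage identity genes went both ways at 0.35 mM, 4 of 24 higher and 4 lower (5 and 6 adjusted over the list alone; adjusted p = 0.66), with the fractalkine receptor Cx3cr1 at -1.64, Adgre1 at -1.29 and the scavenger receptor Cd36 at 2.50. At 2.1 mM 1 was higher, Cd36, and 4 lower (4 and 5 adjusted over the list alone; adjusted p = 0.577), Cx3cr1 at -2.24.

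The autophagy and lysosome list was called at no dose, with 6 of 21 higher and 3 lower at 2.1 mM (6 and 4 adjusted over the list alone; adjusted p = 0.901, median -0.12, mean 0.12), Gabarapl1 at 1.48, Atp6v1h at 1.27 and Tfeb at -1.06. Apoptosis regulators were called at no dose, with 1 of 18 higher and 3 lower at 3.5 mM (3 and 5 adjusted over the list alone; adjusted p = 0.234), Cflar at -1.44 and Xiap at -0.97, the latter turning with the probe set of largest variance (0.06). Osteoclast markers (2 of 10 higher at 2.1 mM, 2 adjusted over the list alone; adjusted p = 0.577), with Mmp9 at 2.40 and Dcstamp at 1.33, and genes of other cell types (2 of 20 higher, S100a8 at 3.70 and Ms4a1 at 0.57; 2 adjusted over the list alone; adjusted p = 0.714) were called at no dose. The mean of the latter list was highest at 0.35 mM, 0.29 (SD 0.0812, n = 3), where 1 of 20 was higher, S100a8 at 4.17 (adjusted p = 0.014; 1 adjusted over the list alone; adjusted p = 0.169 for the list). The metal response list had its lowest adjusted p, 0.0924, at 2.1 mM (1 of 4 higher, Mtf1 at 0.70; 1 adjusted over the list alone), and the metallothionein genes Mt1 and Mt2 passed at no dose, with Mt2 at 0.43 (adjusted p = 0.0544) at 0.35 mM.

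Among the stress genes for which values were to be given, Hspa1a was at 1.44 at 2.8 mM (adjusted p = 0.0698), Ddit3 at 1.14 at 3.5 mM (adjusted p = 0.0586), Egr1 at -1.96 at 2.1 mM (adjusted p = 0.0702) and Atf3 at -0.14 at 3.5 mM (adjusted p = 0.89), and none of these 4 passed at any dose. Fos, an immediate early transcription factor, was at -1.87 at 2.1 mM (adjusted p = 0.026; 0.3 with spike level as a term) and at 1.89 at 3.5 mM (adjusted p = 0.0316; 0.282 with the term). Myc was at 1.42 at 0.35 mM (adjusted p = 0.0362; 0.065 with the term). Without 1 array the Fos call at 2.1 mM was lost in 5 cases, with adjusted p from 0.0551 (0 mM replicate 2) to 0.0979 (2.1 mM replicate 3). The Fos call at 3.5 mM was lost in 7, from 0.0506 (0 mM replicate 2) to 0.0879 (3.5 mM replicate 1). The Myc call was lost in 6, from 0.0554 (0.35 mM replicate 2) to 0.117 (0.35 mM replicate 3).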
